A study of Homo sapiens with 24 samples.

How the data were processed

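RNA from HGC27 cells was sequenced in 24 libraries, 8 groups of 3 replicates. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit and 100 ng went into the Illumina Stranded Total RNA Prep with Ribo-Zero Plus, a kit that depletes ribosomal RNA and keeps strand. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and aligned to hg38 with STAR, with no versions given. The deposited values are raw read counts per gene name, 1 table per library, with 5 closing entries for reads on no gene, ambiguous, of low quality, unaligned or aligned more than once. Reads on no gene were 94.3% to 94.6% of the uniquely aligned reads, ambiguous reads were 2.10% to 3.15% of those on genes, and both stayed out of library sizes except in the alternative named below. The counting program, its strand setting and the annotation release are not stated, and the closing entries have the format of htseq-count. Checked on the files, all values are whole numbers and no value was changed before the tests.

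Samples were grouped by the line and medium in their labels. The comparisons, their tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The comparisons are LPDS against FBS in each line, SG12 and SG21 against SGCTRL in each medium, SGCTRL against parental cells in each medium, the difference in LPDS response of each knockout line from SGCTRL, and the overlaps. Counts were tested in R 4.3.3 with edgeR 4.0.16, whose quasi-likelihood F test was fitted to all 24 libraries with a mean per group, TMM scaling and filterByExpr, which kept 12822 entries. Benjamini-Hochberg adjustment was made within each comparison, and an adjusted p under 0.05 was called a pass. Log2 fold changes carry standard errors, back-calculated as the absolute fold change over the square root of the F statistic. They are approximate, above all where a group has few reads. Levels are CPM with the SD of 3 libraries. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over lists and comparisons), with an estimated correlation and with fry beside it, and members were also counted when adjusted over the list alone. The lists are cholesterol synthesis, sterol uptake and SREBP control, LXR targets, fatty acid and glycerolipid synthesis, lipid droplet, respiratory chain, mitochondrial genome, TCA cycle, fatty acid oxidation, mitochondrial dynamics, glycolysis, lysosome, integrated stress response, ER chaperone, mitosis, DNA replication, interferon, p53, hypoxia, epithelial, mesenchymal, fibroblast, leukocyte, gastric, ribosomal protein and histone genes. They were tested by the genes' own names (25 lists with at least 3 tested entries) and by source gene (17 lists).

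Since the kit keeps strand and the counts lie mostly on the other strand, each entry was assigned a source gene, a step chosen after the data were seen. Entries were matched to GENCODE release 29 (56736 matched), and the source is the gene on the opposite strand whose exons overlap the exons of the entry by at least 50 bases and make up at least 80% of all such overlap. This gave 10141 entries a source, 8747 distinct genes. A source gene was used where its mean level exceeded 5.70 CPM, the 90th percentile of 11404 protein-coding entries with no gene on the other strand, and named by size only above the 99th percentile, 47.8 CPM. Entries whose own gene is likely to supply over 50% of the reads were set aside, which removed 54 protein-coding source genes. Such an overlap samples only part of a gene, so levels cannot be compared between genes, and reads of overlapping genes cannot be told apart fully.

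The naming rule takes TMEM97, NPC1, PGRMC1 and related genes fixed by name in every comparison, and up to 4 passing members of each list by adjusted p (any member of the cholesterol list). It adds the 6 largest rises and 6 largest falls among passing protein-coding entries with an average log2 CPM of at least 2 and the 3 libraries of each group fully apart, which chance gives in 10% of splits of 3 against 3. The last condition is dropped for the response differences. EBP, also named in the rule, was not tested, and some genes the rule names are not reported here. For source genes the same rule was applied, and the text gives part of the genes it names, the larger ones and those of the groups described, chosen after their values were seen.

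Alternatives were DESeq2 1.42.0 size factors and its Wald test, no count filter and a stricter filter (at least 1 CPM in 3 libraries), a spread from the compared groups alone, the replicate number as a block, parental cells as control, and each library left out in turn. Added after seeing the data were a term for the library split, all uniquely aligned reads as library size, the share of reads under the genes' own names as a covariate, SG21 in LPDS with replicate 1 alone, SG21 left out of the overlap of lines, calls against both controls, and list tests by source gene. The own-name share is the median ratio of own-name to antisense reads over 200 abundant pairs, entered on a log2 scale. The library split term can be told from the lines only through SG21 in LPDS, the sole group with libraries on both sides. On simulated counts with the real means and spread, the test of SG12 against SGCTRL in FBS found 68 of 100 genes changed by a log2 fold of 1 and 97 of 100 changed by 2. The test of the SG12 response difference found 39 and 83 of 100, and each test called 4 others. The changed genes were drawn only from entries above a minimum expected count, and no library split was simulated. These shares therefore do not cover entries with lower counts.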

Results

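RNA was sequenced from HGC27, an established human gastric carcinoma cell line, in 24 libraries that fall into 8 groups of 3 replicates. Parental cells and the lines SGCTRL, SG12 and SG21 were each grown for 3 days in medium labelled FBS or LPDS. The labels leave these abbreviations open, and they usually stand for fetal bovine serum and lipoprotein-deficient serum. SGCTRL carries a control guide and, like parental cells, is wild type per the labels. The labels give SG12 and SG21 as knockouts of TMEM97, the sigma-2 receptor, a membrane protein that binds the cholesterol transporter NPC1. The design asks how each line responds to LPDS, and how the knockout lines differ from SGCTRL in each medium. Between 2.4 and 5.54 M reads per library were counted to genes, out of 44.1 to 102 M uniquely aligned reads. At least a single read was counted for 20159 to 24448 gene entries. The replicates are described as independent biological samples without saying what was separate, so the p-values measure only the spread between these libraries.

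Most counts sat on the strand opposite to the gene they are named after. Gene entries held 5.28% to 5.54% of the uniquely aligned reads of a library, and 94.3% to 94.6% fell on no gene. GAPDH, a glycolytic enzyme, had 91.7 counts per M reads (CPM) under its own name, while ENSG00000269968, an antisense transcript inside it, had 42366 CPM. VIM (vimentin) had 112 CPM under its own name and 23667 CPM under VIM-AS1. Among 1768 pairs of a protein-coding gene and an antisense transcript overlapping it, the antisense name had more counts in 1353 pairs (76.5%), with a median ratio of 10. Genes are therefore read here under the entry that overlaps their exons on the other strand, given in parentheses at first mention, a reading chosen after the data were seen. It covers 2809 protein-coding genes, whereas an entry with no gene on the other strand holds mostly leaked or intergenic reads, with a median of 0.318 CPM. The libraries also split in the share of ambiguous reads among reads on genes, 2.10% to 2.24% in 8 libraries (all 6 of SGCTRL, and SG21 in LPDS replicates 2 and 3) and 2.58% to 3.15% in the other 16.

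TMEM97 RNA was lowest in both knockout lines in FBS and was not lower in SG12 in LPDS. TMEM97 (chromosome 17, 28319095 to 28328685 in hg38) is read under IFT20, which shares 361 bases with its 3' end. Its mean level in FBS was 105 ± 14.9 CPM (SD, n = 3) in parental cells, 131 ± 12.8 in SGCTRL, 52.8 ± 4.1 in SG12 and 76 ± 2.96 in SG21. In LPDS it was 153 ± 14.9, 162 ± 11.5, 195 ± 16.8 and 124 ± 3.92 CPM in the same order. Against SGCTRL in FBS, the log2 fold change was -1.30 ± 0.13 (SE) in SG12 (edgeR adjusted p = 1.58e-11) and -0.78 ± 0.12 in SG21 (adjusted p = 5.61e-06). In LPDS it was 0.26 ± 0.12 in SG12 (adjusted p = 0.155) and -0.39 ± 0.12 in SG21 (adjusted p = 0.0241). The entry named TMEM97, which holds the reads of IFT20, averaged 61.7 to 91.5 CPM over the 8 groups and passed the test in 4 of 12 comparisons. The guides' target sites are not given and RNA at the 3' end does not show an edit upstream, so these levels do not check the knockout labels. Both SG21 calls are lost with a term for the library split, in FBS at a log2 fold change of -0.73 (adjusted p = 0.0811) and in LPDS at -0.37 (adjusted p = 0.0614). The LPDS call is lost too with parental cells as control (-0.31, adjusted p = 0.0909) and without replicate 1 or 2 of either group.

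**Figure D1:**
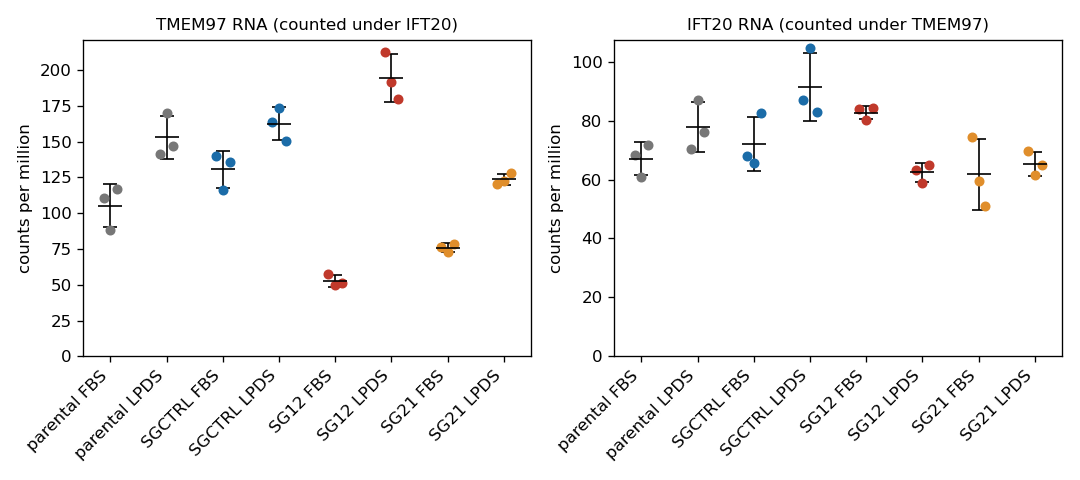
CPM in each of the 24 libraries (points), with the mean and SD of each group of 3 (bars), for TMEM97 RNA, counted under IFT20 (left), and IFT20 RNA, counted under TMEM97 (right). TMEM97 RNA averaged 52.8 CPM in SG12 in FBS and 195 CPM in SG12 in LPDS.

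In all 4 lines, LPDS raised genes that make cholesterol. HMGCS1 (ENSG00000261604), which makes the HMG-CoA of the sterol pathway, rose by a log2 fold change of 1.26 ± 0.10 (SE) in parental cells, 0.97 ± 0.10 in SGCTRL, 2.47 ± 0.10 in SG12 and 1.18 ± 0.10 in SG21. LSS (ENSG00000223901), the enzyme that closes the sterol rings, rose by 1.03 ± 0.10, 0.77 ± 0.10, 2.07 ± 0.10 and 1.08 ± 0.10 in the same order. ACAT2 (TCP1), the cytosolic acetoacetyl-CoA thiolase, rose by 0.64 ± 0.10, 0.85 ± 0.10, 1.60 ± 0.11 and 0.90 ± 0.10. The list of cholesterol synthesis enzymes had 6 measured members and moved up in every line, with camera adjusted p-values of 5.16e-13, 9.57e-15, 5.48e-32 and 9.86e-14 for parental, SGCTRL, SG12 and SG21. With an estimated correlation the adjusted p was 9e-05, 5.93e-05, 6.39e-07 and 6.1e-05. Of the 6 members 4, 4, 5 and 4 rose, and 5, 5, 5 and 4 passed when adjusted over the list alone. IDI1 (IDI2-AS1), the isopentenyl diphosphate isomerase, did not pass in SGCTRL (0.81, adjusted p = 0.0656) and SG21 (0.21, adjusted p = 0.704), but passed with a term for the library split (0.81, adjusted p = 2.79e-06, and 0.82, adjusted p = 0.00116). FDFT1 (ENSG00000255046), squalene synthase, did not pass in any line, with log2 fold changes of -0.19, -0.22, 0.21 and -0.24.

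**Figure D2:**
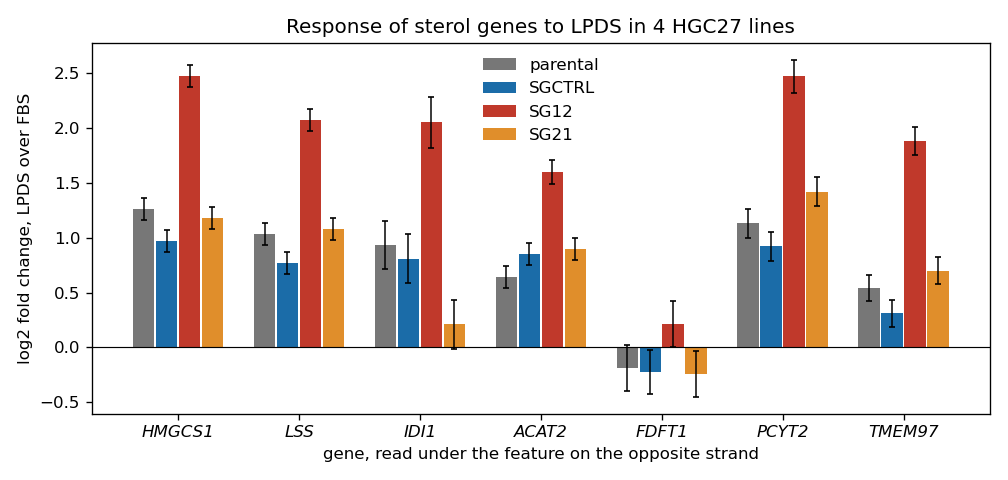
Log2 fold change of LPDS over FBS (bars) with its standard error (lines) for 7 genes in parental, SGCTRL, SG12 and SG21 cells, 3 libraries per group. HMGCS1 rose by 2.47 in SG12 and by 0.97 to 1.26 in the other lines, and IDI1 in SGCTRL and SG21, TMEM97 in SGCTRL and FDFT1 in every line did not pass the test.

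Other lipid genes rose with LPDS in every line, and a set of hypoxia genes fell in SGCTRL, SG12 and SG21. PCYT2 (NPB), an enzyme of phosphatidylethanolamine synthesis, rose by 1.13, 0.92, 2.47 and 1.42 in parental, SGCTRL, SG12 and SG21. ACLY (ENSG00000274630), which makes cytosolic acetyl-CoA, rose by 0.52, 0.56, 1.05 and 0.68, and LPCAT3 (EMG1), a phospholipid acyltransferase, by 0.77, 0.72, 0.68 and 0.64. The sterol uptake list (5 measured members) moved up in parental cells (camera adjusted p = 0.00056, and 0.0283 with an estimated correlation) and SG12 (0.000419 and 0.0293). The fatty acid synthesis list (5 measured members) moved up in parental cells (0.000614 and 0.0137) and SG21 (0.000246 and 0.00852). The hypoxia list (7 measured members) moved down in SGCTRL (4.23e-06 and 0.0309), SG12 (1.06e-07 and 0.0144) and SG21 (1.94e-12 and 0.00191), where 3, 5 and 5 members fell. In parental cells its camera adjusted p was 0.0268, and the adjusted p = 0.255 with an estimated correlation. LOX (SRFBP1), lysyl oxidase, fell by 0.63, 1.07 and 0.82 on the log2 scale in SGCTRL, SG12 and SG21, and P4HA2 (P4HA2-AS1), a collagen prolyl hydroxylase, fell by 0.41, 1.55 and 0.71. The glycolysis list (6 measured members) moved down in SGCTRL (0.017, and adjusted p = 0.193 with an estimated correlation) and SG21 (0.013, and adjusted p = 0.177 with an estimated correlation).

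Altogether 583 of 12822 entries passed in parental cells (282 higher and 301 lower in LPDS), 299 in SGCTRL (169 and 130), 2882 in SG12 (1476 and 1406) and 491 in SG21 (240 and 251). The larger side in SG12 turned without any single library of its 6, and that in parental cells without FBS replicate 2 or LPDS replicate 1 or 3. In all 4 lines 49 entries passed in the same direction, 36 higher and 13 lower, where independent lists would share 0.00801 and 0.00655. Besides the lipid genes, LBHD1 (UQCC3) rose by 2.51, 2.42, 2.72 and 2.30 in parental, SGCTRL, SG12 and SG21, PRUNE2 (PCA3) by 1.69, 1.49, 1.87 and 1.67, and IER2 (ENSG00000267598), an immediate early gene, by 0.80, 0.97, 1.88 and 0.96. ANKRD37 (UFSP2), a hypoxia-induced gene, fell by 0.94, 1.01, 0.62 and 1.44 on the log2 scale, LOXL2 (LOXL2-AS1), a lysyl oxidase relative, fell by 0.50, 0.68, 0.31 and 0.61, and CCM2L (ENSG00000226239) fell by 0.71, 0.80, 0.61 and 0.71. SLC7A11 (SLC7A11-AS1), the cystine transporter, rose in parental cells (0.73 ± 0.11) and SG21 (0.77 ± 0.11) and fell by 1.10 ± 0.11 in SG12. Among entries under their own name, the first by size included NIPSNAP3B (3.28 ± 0.44 in SGCTRL) and GSS (3.05 ± 0.37 in SG12) among rises, and GRM4 (-2.92 ± 0.38 in SGCTRL) and MCM4 (-2.62 ± 0.50 in parental cells) among falls. The parental count was 159 without LPDS replicate 3, 180 without FBS replicate 2, 323 without LPDS replicate 1, 248 with a spread from its 6 libraries alone and 93 with the leaked share of each library as a covariate. The SGCTRL count was 152 to 193 without any of FBS replicates 1 to 3 or LPDS replicates 2 and 3, and 793 with its own spread. The SG21 count was 221 to 846 without any single library of its 6 and 91 with a term for the library split. That term ends the SG21 call of IER2 (0.75), and the covariate ends the parental calls of LOXL2 (-0.37), CCM2L (-0.44) and MCM4 (-2.23). Lost without some single library are P4HA2 in SGCTRL (adjusted p = 0.0437), LOXL2 in SG12 (adjusted p = 0.0378), and CCM2L in SG12 and parental cells.

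SG12 responded to LPDS differently from SGCTRL, with a larger rise of sterol genes. The difference between the responses was 1.5 ± 0.14 (log2, SE) for HMGCS1 (adjusted p = 4.02e-11), 1.31 ± 0.14 for LSS, 1.24 ± 0.31 for IDI1 and 0.75 ± 0.15 for ACAT2. TMEM97 differed by 1.57 ± 0.17 (adjusted p = 3.39e-09) and SREBF2 (SREBF2-AS1), a sterol-regulated transcription factor, by 0.72 ± 0.15 (adjusted p = 0.000544). HMGCS1 averaged 485 ± 73.2 CPM (SD, n = 3) in SG12 in FBS, against 1967 ± 193 in SGCTRL, and 2687 ± 180 against 3864 ± 198 in LPDS. The cholesterol list moved up in this difference (median 1.26, camera adjusted p = 7.34e-12, and 0.000118 with an estimated correlation), with 5 of 6 members higher, as many as when adjusted over the list alone. The entry named TMEM97, which holds IFT20 reads, differed by -0.75 ± 0.20 (adjusted p = 0.0112).

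Some genes of DNA replication also rose with LPDS in SG12 relative to SGCTRL, and genes of the integrated stress response fell relative to it. MCM2 (ENSG00000285600), a subunit of the replicative helicase, differed by 1.66 ± 0.15 (adjusted p = 3.52e-12), CCNE2 (INTS8), a cyclin of S phase entry, by 1.39 ± 0.25 and LIG1 (ENSG00000269534), DNA ligase 1, by 1.18 ± 0.21. The replication list as a whole (9 measured members) had a camera adjusted p of 0.0187, and the adjusted p = 0.272 with an estimated correlation, with 3 members higher and 1 lower. The stress response list (7 measured members) moved down (camera adjusted p = 3.59e-08, and 0.00411 with an estimated correlation). Its members SLC7A11, MTHFD2 (ENSG00000264324), a mitochondrial folate enzyme, ALDH1L2 (NOPCHAP1), another of that pathway, and VEGFA (ENSG00000272114) differed by -1.14 ± 0.15, -1.0 ± 0.11, -1.08 ± 0.23 and -0.89 ± 0.13. VEGFA is also a hypoxia gene. In SG12 itself 6 of the 7 members fell with LPDS (adjusted p = 0.00191 with an estimated correlation). P4HA2, of the hypoxia list, differed by -1.14 ± 0.17. Among the largest differences by source gene, a reading chosen after the data were seen, were WARS1 (ENSG00000258666), tryptophanyl-tRNA synthetase, at -2.59 ± 0.14, SAMD11 (NOC2L) at -2.35 ± 0.15, SNTB1 (MTBP) at -2.13 ± 0.17, AIMP2 (EIF2AK1), a tRNA synthetase scaffold, at -1.91 ± 0.14 and FXYD6 (FXYD6-AS1) at 2.20 ± 0.24. Under their own names the planned rule gave CDR1 at -7.14 ± 0.99 and L3MBTL2 at -4.65 ± 0.29. The CDR1 entry averaged 0.105 CPM in SG12 in LPDS, so its fold is not precise. In all, 1376 entries passed, 671 higher and 705 lower, and the SREBF2 difference is lost with parental cells as control (0.35, adjusted p = 0.135).

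SG21 differed little from SGCTRL in its response to LPDS. The differences were 0.20 ± 0.14 for HMGCS1 (adjusted p = 0.746), 0.32 ± 0.14 for LSS and 0.39 ± 0.17 for TMEM97 (adjusted p = 0.536). Only 6 entries passed, 2 higher and 4 lower, among them MCM2 (0.77 ± 0.14, adjusted p = 0.0214), SLC7A11 (0.73 ± 0.15, adjusted p = 0.0452), TPP1 (ENSG00000255680), a lysosomal peptidase (-0.80 ± 0.17, adjusted p = 0.0465), and the RHBDL1 entry (-2.01 ± 0.40, adjusted p = 0.0399). With parental cells as control 88 entries passed, 34 higher and 54 lower. The SLC7A11 difference was then 0.04 (adjusted p = 0.945) and that of TPP1 -0.54 (adjusted p = 0.107), so neither passed. No list held with an estimated correlation, and the count ran from 0 to 250 when single libraries were left out, highest without SG21 LPDS replicate 1. With a term for the library split edgeR called 0 entries. At an unadjusted p under 0.05 there were 578, fewer than a 0.05 share of the 12822 tested, the number expected with no difference. DESeq2 called 32 without that term. Under the term MCM2 was at 0.56, SLC7A11 at 0.68, TPP1 at -0.67 and RHBDL1 at -2.20, so these calls were lost with the direction of the folds kept.

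In FBS, SG12 had less RNA of sterol genes and of some replication genes than SGCTRL. HMGCS1 was lower by a log2 fold change of -2.02 ± 0.10 (SE, adjusted p = 4.79e-21), LSS by -1.07 ± 0.10 and ACAT2 by -0.79 ± 0.11. PCYT2 was lower by -2.03 ± 0.15. IDI1 was at -0.64 ± 0.22 (adjusted p = 0.0448), a call lost under DESeq2's size factors (adjusted p = 0.0528), a stricter count filter, the leaked share as a covariate, and without any single library. The cholesterol list moved down (camera adjusted p = 5.88e-12, and 0.000118 with an estimated correlation), with 5 of 6 members lower, the same number adjusted over the list alone. Against parental cells the median of the list was -0.82, beside -0.93 against SGCTRL. MCM2 was lower by -2.22 ± 0.11 (adjusted p = 1.44e-22), CCNE2 by -1.76 ± 0.18, LIG1 by -1.50 ± 0.15 and RFC5 (ENSG00000277873), a clamp loader subunit, by -0.91 ± 0.15. Of 9 measured replication genes 5 were lower and 2 higher, with a camera adjusted p of 4.95e-05, and the adjusted p = 0.0921 with an estimated correlation. Of 4 mitosis genes 3 were lower, among them CCNA2 (EXOSC9), cyclin A2, at -1.06 ± 0.13 and PLK1 (ENSG00000261266), a mitotic kinase, at -0.79 ± 0.12 (list camera adjusted p = 0.0243, and adjusted p = 0.163 with an estimated correlation). Of 5 ER chaperone genes 3 were lower, among them PDIA6 (ATP6V1C2), a disulfide isomerase, at -0.73 ± 0.08 (0.00766, and adjusted p = 0.163 with an estimated correlation).

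Other large changes of SG12 in FBS lay outside these lists. FXYD6, a regulator of the sodium pump, was lower by -4.10 ± 0.18, BAIAP2L1 (BRI3), an actin and membrane adaptor, by -3.18 ± 0.14 and RAD54L (LRRC41), a recombination helicase, by -2.09 ± 0.12. S100A1 (S100A13), a calcium-binding protein, was higher by 2.65 ± 0.19, NKD1 (ENSG00000205414), a Wnt antagonist, by 2.18 ± 0.17, BDNF (BDNF-AS), a neurotrophin, by 2.00 ± 0.17 and NRP1 (ENSG00000238258), a semaphorin co-receptor, by 1.96 ± 0.14. Under their own names, YKT6 was lower by -4.94 ± 0.29 and TNFAIP2 by -6.12 ± 0.46, while H3C6 was higher by 4.20 ± 0.64 and L3MBTL2 by 4.13 ± 0.20. In all, 3236 entries passed, 1553 higher and 1683 lower, and more were higher than lower without any single library. With a term for the library split 842 passed, and the PLK1 (-0.60) and TNFAIP2 (-3.64) calls were lost.

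In FBS, SG21 had less RNA of mesenchymal genes than SGCTRL and a mixed picture in sterol genes. VIM was lower by -0.77 ± 0.15 (adjusted p = 0.00138), CD44 (CD44-AS1), a hyaluronan receptor, by -0.74 ± 0.13 and TWIST1 (ENSG00000232821), a mesenchymal transcription factor, by -0.74 ± 0.17. The mesenchymal list moved down (camera adjusted p = 0.00936, and 0.0463 with an estimated correlation), with 4 of 7 members lower and 1 higher, 6 passing when adjusted over the list alone. HMGCS1 was lower by -0.68 ± 0.10 (adjusted p = 1.09e-06) and NPC1 (RMC1), which exports cholesterol from lysosomes, by -0.80 ± 0.17, whereas ACAT2 was higher by 0.86 ± 0.10. The cholesterol list did not move as a set (camera adjusted p = 0.977). Against parental cells HMGCS1 was higher instead (0.35, adjusted p = 0.00628), as was LSS (0.52, adjusted p = 8.19e-05), which against SGCTRL was at -0.16 ± 0.10 (adjusted p = 0.287). By size, POLL (DPCD), a repair polymerase, was lower by -2.01 ± 0.13, EFNB2 (ENSG00000284966), ephrin B2, by -1.65 ± 0.12 and ACTR1A (ENSG00000273262), a dynactin subunit, by -1.50 ± 0.11. Under their own names the planned rule gave CDR1 at 3.54 ± 0.49 and PSAT1 at -3.03 ± 0.77. In all, 1800 entries passed, 942 higher and 858 lower, with 3101 against parental cells and 157 with a term for the library split, which ends the calls of HMGCS1 (-0.48), ACAT2 (0.53), VIM (-0.31), TWIST1 (-1.04) and the PSAT1 entry (-2.68). Parental cells as control end the call of NPC1 (-0.29).

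Both knockout lines differed from SGCTRL in the same direction in 669 entries in FBS, 383 higher and 286 lower, and in opposite directions in 184. Lower in both were TMEM97, THY1 (THY1-AS1), a cell surface glycoprotein also used as a fibroblast marker (-1.22 ± 0.11 in SG12 and -0.82 ± 0.11 in SG21), and PIEZO2 (ENSG00000264843), a mechanosensitive channel (-1.25 ± 0.15 and -0.91 ± 0.15). Higher in both were ESPN (TNFRSF25), an actin-bundling protein (2.42 ± 0.18 and 0.90 ± 0.18), CCDC3 (ENSG00000285520), a secreted protein (1.41 ± 0.13 and 1.42 ± 0.13), and C21orf91 (ENSG00000244676; 1.21 ± 0.15 and 0.87 ± 0.15). Under their own names PLXNA4 (2.55 ± 0.44 and 3.12 ± 0.43) and ULK2 (1.68 ± 0.35 and 3.06 ± 0.33) were higher. Also higher in both were UQCRB (UQCRB-AS1; 1.54 ± 0.33 and 1.48 ± 0.33), ATP5ME (MYL5; 1.22 ± 0.33 and 1.09 ± 0.33) and UQCRQ (GDF9; 0.84 ± 0.12 and 0.73 ± 0.12) of the respiratory chain, and TMA7 (ENSG00000244380; 1.28 ± 0.34 and 1.48 ± 0.33). The respiratory chain list moved up in both (camera adjusted p = 0.00406 in SG12 and 0.0187 in SG21), with the adjusted p = 0.186 and 0.267 with an estimated correlation. Against parental cells, whose libraries lie on the same side of the library split as SG12 and SG21 in FBS, the UQCRB values were 0.10 (adjusted p = 0.851) and 0.04 (adjusted p = 0.951), and ATP5ME (0.13 and 0.01), UQCRQ (0.13 and 0.03) and TMA7 (0.09 and 0.29) did not pass either. In simulations that drew unchanged lines and their controls alike from the SGCTRL means, the lines shared a median of 0 entries. The simulations held no library split, so a shift of the real SGCTRL libraries is not covered. Lines without any change pass almost nowhere after adjustment, so an overlap near 0 follows from the setting. It does not measure what shared controls add where many entries differ. Independent lists would share 114 higher and 113 lower. The correlation of the fold changes was 0.34, beside 0.50 in the simulations, their covariance was 0.229, beside 0.0703, and the SGCTRL libraries are too few to split, so part of the overlap may come from them. Of the 669 entries, those that also passed against parental cells in both lines numbered 190, and 50 passed in both lines with a term for the library split. That term ends the calls of THY1 (-0.64), ESPN (1.05) and C21orf91 (0.53) in SG21 and of ULK2 (0.79) in SG12 and UQCRQ in both (0.30 and 0.19), and turns UQCRB, ATP5ME and TMA7 to negative values that do not pass. ATP5ME in SG21 (adjusted p = 0.0355) is also lost without any single library.

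In LPDS, SG12 had less RNA of stress response genes than SGCTRL and more of some mesenchymal genes. SLC7A11 was lower by -0.90 ± 0.11 (SE, adjusted p = 1.43e-08), MTHFD2 by -0.73 ± 0.08 and SLC7A5 (ENSG00000260466), an amino acid transporter, by -1.01 ± 0.21. The stress response list moved down (camera adjusted p = 2.34e-07, and 0.00633 with an estimated correlation), with 5 of 7 members lower and 6 when adjusted over the list alone. ZEB2 (ZEB2-AS1), a mesenchymal transcription factor, was higher by 0.94 ± 0.18, TWIST1 by 0.89 ± 0.17 and CD44 by 0.74 ± 0.12. The mesenchymal list moved up (0.00107 and 0.0156), with 3 of 7 members higher and 4 when adjusted over the list alone. Of the sterol genes, HMGCS1 was at -0.52 ± 0.10 (adjusted p = 0.000129) and LSS at 0.24 ± 0.09 (adjusted p = 0.104), which passed with the library split term (0.59) and with parental cells as control (0.65). By size, S100A1 was higher by 3.49 ± 0.19 and BCS1L (ZNF142), a respiratory chain assembly factor, by 1.83 ± 0.16. BAIAP2L1 was lower by -2.43 ± 0.13, SNTB1, a syntrophin, by -2.22 ± 0.12 and, under its own name, YKT6 by -6.51 ± 0.34. In all, 1428 entries passed, 658 higher and 770 lower, with 927 and 933 without SGCTRL LPDS replicate 1 or 2 and 200 with a term for the library split. That term ends the calls of HMGCS1 (-0.32), SLC7A5 (-0.54), ZEB2 (0.46), TWIST1 (0.58) and CD44 (0.47). Parental cells as control end those of TWIST1 (0.31) and CD44 (0.34) and turn HMGCS1 to 0.22 (adjusted p = 0.144).

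In LPDS, SG21 had more RNA of replication genes than SGCTRL and less of mesenchymal, lysosomal and ribosomal protein genes. MCM2 was higher by 0.94 ± 0.10 (SE, adjusted p = 7.92e-10), RRM1 (RRM1-AS1), a ribonucleotide reductase subunit, by 0.66 ± 0.13 and LIG1 by 0.65 ± 0.14. In all, 8 of 9 measured replication genes were higher (camera adjusted p = 7.29e-08, and 0.0309 with an estimated correlation). TWIST1 was lower by -1.02 ± 0.18, CD44 by -0.96 ± 0.13 and VIM by -0.88 ± 0.15, and 3 of 7 mesenchymal genes were lower (0.000134 and 0.00633). Among 7 lysosomal genes 4 were lower (0.00228 and 0.0354), with CTSA (ENSG00000271984), a carboxypeptidase, at -0.81 ± 0.11, TPP1 at -0.55 ± 0.12 and HEXA (ENSG00000261460), a hexosaminidase subunit, at -0.38 ± 0.11. Among 13 ribosomal protein genes 7 were lower (0.000335 and 0.0353), with RPL32 (CAND2) at -1.16 ± 0.20, RPS28 (KANK3) at -0.91 ± 0.15 and RPS3A (SH3D19) at -0.68 ± 0.09. Adjusted over the list alone, 8, 3, 4 and 7 members of these lists passed. HMGCS1 was at -0.48 ± 0.10 (adjusted p = 0.000417) and NPC1 at -0.69 ± 0.16, and ACAT2 was higher by 0.91 ± 0.10. By size, POLL was lower by -1.88 ± 0.13, PROCR (ENSG00000278367), the protein C receptor, by -1.88 ± 0.17, WIPI1 (ARSG), an autophagy protein, by -1.69 ± 0.14 and, under its own name, LPIN2 by -3.61 ± 0.58. In all, 1401 entries passed, 704 higher and 697 lower. Parental cells as control turn HMGCS1 to 0.27 (adjusted p = 0.0636) and end the calls of RRM1 (0.33) and HEXA (-0.25), the last of which is also lost with the library split term and without SGCTRL LPDS replicate 1 or 2 or SG21 LPDS replicate 1.

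Both knockout lines differed from SGCTRL in the same direction in LPDS in 286 entries, 140 higher and 146 lower, and in opposite directions in 132. ACTA2 (ACTA2-AS1), smooth muscle actin, was lower by -1.62 ± 0.14 in SG12 and -1.76 ± 0.14 in SG21, THY1 by -1.07 ± 0.11 and -0.66 ± 0.11, and PIEZO2 by -0.93 ± 0.14 and -0.90 ± 0.14. CCDC3 was higher by 1.20 ± 0.13 and 1.72 ± 0.13, ESPN by 1.61 ± 0.18 and 1.17 ± 0.18, C21orf91 by 0.91 ± 0.15 and 0.98 ± 0.15, and the ATOSB entry by 3.19 ± 0.71 and 3.21 ± 0.71. TNFAIP2 under its own name was lower by -7.15 ± 0.49 and -4.92 ± 0.39. In the like simulations, again without a library split, unchanged lines shared a median of 0 entries and at most 1. Here too so low an overlap follows from lines without any change, and does not measure what shared controls add. Independent lists would share 36.1 higher and 41.9 lower. The correlation was 0.33, beside 0.48 in the simulations, and the covariance 0.163, beside 0.0654. Against parental cells as well 110 entries passed in both lines, the count was 189 and 176 without SGCTRL LPDS replicate 1 or 2, and with a term for the library split 75 passed. That term ends the calls of C21orf91 (0.58), TNFAIP2 (-4.66) and ATOSB (2.41) in SG12.

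SGCTRL had more RNA than parental cells of stress response genes in FBS and of HMGCS1 and LSS in both media. SLC7A11 was higher by 0.93 ± 0.11 in FBS (SE, adjusted p = 2.62e-08), VEGFA by 0.55 ± 0.10 and MTHFD2 by 0.40 ± 0.08. The stress response list moved up (camera adjusted p = 2.22e-05, and 0.0188 with an estimated correlation), with 5 of 7 members higher, the same number adjusted over the list alone. HMGCS1 was higher by 1.03 ± 0.10 in FBS and 0.75 ± 0.10 in LPDS, and LSS by 0.68 ± 0.10 and 0.42 ± 0.10. The cholesterol list moved up in LPDS (0.00423 and 0.0469), while in FBS its adjusted p = 0.163 with an estimated correlation, after a camera adjusted p of 0.0499. FXYD6 was higher by 1.04 ± 0.14 in FBS and 0.95 ± 0.14 in LPDS, CCM2L by 1.09 ± 0.16 and 1.00 ± 0.16 and, under its own name, TNFAIP2 by 1.82 ± 0.29 and 1.94 ± 0.29. UQCRB was lower by -1.44 ± 0.33 in FBS, and UQCRQ by -0.71 ± 0.12 in FBS and -0.64 ± 0.12 in LPDS. Among the largest falls under their own names in FBS were EEF1B2, a translation factor, at -3.65 ± 0.56, the linker histone H1-3 at -3.64 ± 0.47, and the ribosomal proteins RPL37 at -3.48 ± 0.38 and RPS24 at -3.39 ± 0.42.

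Between SGCTRL and parental cells 2351 entries passed in FBS, 1057 higher and 1294 lower, and 104 in LPDS, 58 and 46. In each library, the 200 most abundant pairs of gene and antisense transcript gave a median ratio of own-name to antisense reads. It was 1.70%, 2.58% and 1.94% in the parental FBS libraries, beside 0.92% to 1.65% in the other 21. Of the 714 entries with no gene on the other strand that passed in FBS, 583 were lower in SGCTRL. The FBS count was 1100 without parental FBS replicate 2, 1421 without SGCTRL FBS replicate 3, 133 with a term for the library split and 88 with the leaked share as a covariate. Both end the calls of NPC1 (0.51 before, 0.92 with the split term and -0.14 with the covariate), MTHFD2 (0.32 and 0.42), UQCRB (0.37 and -1.65), EEF1B2 (-3.67 and -3.06), RPL37 (-3.20 and -1.87) and TNFAIP2 (-0.67 and 1.78). The split term also ends those of LSS (0.33), FXYD6 (0.71), CCM2L (0.73), UQCRQ (-0.16) and RPS24 (-3.17), and the covariate those of VEGFA (0.53) and H1-3 (-1.63). The calls of EEF1B2, RPS24 and RPL37 under the split term were among those lost with little change in the fold. So were those of MTHFD2, TNFAIP2, VEGFA and UQCRB under the covariate. The LPDS count was 24, 39, 48 and 62 without SGCTRL replicate 2, parental replicate 1, parental replicate 2 and SGCTRL replicate 1, and 1 with the library split term, under which the LPDS calls named here are lost, with HMGCS1 at 0.54, LSS at 0.06, FXYD6 at 0.62, CCM2L at 0.64, UQCRQ at -0.10 and TNFAIP2 at -0.54. LSS in LPDS (adjusted p = 0.0153) is also lost under a stricter count filter and without any of 4 single libraries.

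The lists fixed in advance were also tested by the genes' own names, as planned, and those readings rest mainly on opposite-strand or leaked reads. There, 44 of 300 tests of 25 lists passed with camera, and 0 held with an estimated correlation, where 73 passed with fry. The cytosolic ribosomal protein list (63 entries) was lower in SGCTRL than in parental cells in FBS (median -1.87, camera adjusted p = 1.53e-40, and adjusted p = 0.177 with an estimated correlation). So were the replication-dependent histones (13 entries, median -2.58, 6.79e-19, and adjusted p = 0.177 with an estimated correlation). The mitochondrial genome genes (13 entries) were higher in SG12 than in SGCTRL in LPDS (median 1.86, 5.33e-19, and adjusted p = 0.195 with an estimated correlation) and lower in SG21 in LPDS than in FBS (median -1.63, 1.57e-19, and adjusted p = 0.195 with an estimated correlation). Lipid droplet genes (5 entries) responded more to LPDS in SG12 (0.016, and adjusted p = 0.377 with an estimated correlation). Glycolysis, fibroblast, ER chaperone and mitochondrial dynamics lists were lower in SGCTRL than in parental cells in FBS (8.36e-06, 0.000694, 0.00111 and 0.00146, with adjusted p = 0.322, 0.236, 0.286 and 0.192 with an estimated correlation). The cholesterol, sterol uptake, LXR, lysosome, TCA cycle, fatty acid oxidation, p53, epithelial, interferon and leukocyte lists passed camera in no comparison by own name. By source gene, the TCA cycle, fatty acid oxidation, mitochondrial dynamics and p53 lists passed camera in no comparison. The gastric differentiated cell list had 1 tested entry and was not tested as a set. Of the entries fixed by name, NPC1 passed in 2 comparisons and PGRMC1 in 0 of 12, with PGRMC1 log2 fold changes from -1.43 to 1.24. With parental cells as control PGRMC1 was lower in FBS in SG12 (-1.74, adjusted p = 0.0295) and SG21 (-2.16, adjusted p = 0.0079). This entry is not read for a source gene and averaged 6.33 ± 3.43 CPM (SD) in parental cells in FBS. In the same comparisons 599 of 807 and 787 of 1008 passing entries with no gene on the other strand were lower, so leaked reads may contribute.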

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

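The tests of the library split, the one within SG21 in LPDS included, and of leaked reads were chosen after the results were seen; the comparison of SG12 with SG21 was chosen after each had been compared with SGCTRL, and the splits of the libraries were planned.

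The response to LPDS differed between SG12 and SGCTRL in 1376 entries and between SG21 and SGCTRL in 6, by a test of the difference itself. In SG12 the sterol-related differences (log2) were HMGCS1 1.5, LSS 1.31, IDI1 1.24, ACAT2 0.75, SREBF2 0.72 and TMEM97 1.57, with -0.75 for the entry named TMEM97. Those of DNA replication were MCM2 1.66, CCNE2 1.39 and LIG1 1.18. Those of the stress response and hypoxia lists were SLC7A11 -1.14, MTHFD2 -1.0, ALDH1L2 -1.08, VEGFA -0.89 and P4HA2 -1.14. Among the largest by size were FXYD6 2.20, WARS1 -2.59, SAMD11 -2.35, SNTB1 -2.13 and AIMP2 -1.91, and, under their own names, CDR1 -7.14 and L3MBTL2 -4.65. In SG21 they were MCM2 0.77, SLC7A11 0.73, TPP1 -0.80 and the RHBDL1 entry -2.01, of which SLC7A11 (0.04) and TPP1 (-0.54) did not pass with parental cells as control.

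The larger response of SG12 was weighed against a library effect, leaked reads and an equal loss of TMEM97. The response difference of SG12 against parental cells, whose libraries lie on the same side of the split, called 1103 entries. SG12, SGCTRL and parental cells each lie on a single side in both media. A constant shift by the split thus cancels in these differences, and the test could not implicate it. A shift particular to SG12 in LPDS, with ambiguous shares of 2.99% to 3.15% beside 2.63% to 2.80% in FBS, is not covered. Leaked reads are argued against by 1421 entries called with the own-name share of each library as a covariate. A loss of TMEM97 of like effect in both knockout lines predicts like responses, and the responses of SG12 and SG21 differed in 1682 entries, with HMGCS1 at 1.29 ± 0.14 (log2, SE, adjusted p = 2.34e-09). SG21 in LPDS has libraries on both sides of the split, and this comparison was not fitted with the split term. Part of the count may thus come from the split. With that term the rise in SG21 was 1.04 for HMGCS1 (1.18 without it) and 0.82 for IDI1 (0.21 without it). A difference between the lines that the guides or clones brought may account for the larger response of SG12, a hypothesis left untested, as is an unequal degree of knockout.

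SGCTRL and parental cells differed in 2351 entries in FBS and in 104 in LPDS, a contrast whose difference between media was not tested. The library split alone is argued against as the cause of the contrast, since the lines lie on the same 2 sides in LPDS, where 104 entries passed. Leaked reads may contribute in FBS. Of the passing entries with no gene on the other strand, 81.7% were lower in SGCTRL, and with the own-name share as a covariate 88 entries passed, a term that also takes up part of the group difference. No biological explanation was tested.

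The respiratory chain list had medians of 0.39 in SG12 and 0.47 in SG21 against SGCTRL in FBS, a set that does not pass with an estimated correlation (adjusted p = 0.186 and 0.267). Against parental cells the medians were 0.13 and 0.02, and 9 of 12 members were lower in both SG21 LPDS libraries on the SGCTRL side of the split than in replicate 1. These values could come from the library split, and a change particular to SGCTRL stays open as well. The cause cannot be told apart, since every SGCTRL library lies on a single side and only 3 SG21 LPDS libraries span both.

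For each comparison of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split was the highest in each of those comparisons (1 of 10), with 248, 793, 2922 and 402 entries for LPDS in parental, SGCTRL, SG12 and SG21 cells against at most 0, 38, 0 and 1 in another split. It called 3229 and 2453 for SG12 and SG21 in FBS, 2139 and 1270 in LPDS, and 1678 and 356 for SGCTRL against parental cells in FBS and LPDS, against at most 0, 0, 0, 0, 0 and 3. For the SG12 response difference 1 of 50 splits, the real one, reached 1861 entries, which excludes chance at that share. Another split, with lines exchanged within a medium, called 1486, so a structure of the samples can give a count near the real one. For SG21 8 of 50 splits reached 17, with 612 the highest, so chance is not excluded, and such a split points to a structure of the samples. The overlap of both knockout lines in FBS, 819 in a fit of SGCTRL, SG12 and SG21 in FBS alone, was reached by 2 of 50 splits, the real one included. That share is under 0.05, but the other split called 2123. With a count above the real one under exchanged labels, chance is not excluded for an overlap of this size, and the same structure is pointed to. In LPDS, in the like fit, 4 of 50 reached 316, with 402 the highest, so chance is not excluded. The overlap of all 4 lines, 49 entries, was reached by 1 of 50 splits, the real one, with 0 in every other drawn. Those splits mix the media within lines, and splits of single lines called few or no entries, so hardly any overlap could arise. The share therefore speaks only against no effect of medium at all. It cannot decide whether lines with separate responses would share as many entries.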

How the results depend on the processing

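The library split term, uniquely aligned reads as library size, the own-name share as a covariate, SG21 LPDS replicate 1 alone, SG21 left out, parental cells as control for single genes, calls against both controls and lists by source gene were tests chosen after seeing the data; the others were planned. Of 329 named values 259 passed, 229 of them under every alternative set in advance, single libraries left out included, and 0 were reversed under those. DESeq2's size factors, the stricter filter and the replicate block left the totals of passing entries within 1.5 times, but not always their balance. The stricter filter gave 44 higher and 77 lower for SGCTRL against parental cells in LPDS (58 and 46 in the original fit). The larger side for SG12 against SGCTRL in FBS (1553 and 1683 before) turned there (1857 and 1401), with DESeq2's size factors (1677 and 1574) or Wald test, the compared groups alone or the covariate, and with any single library out (1507 and 1148 without SGCTRL FBS replicate 1). That for LPDS in SG12 (1476 and 1406 before) turned under the stricter filter (1248 and 1718), with DESeq2's size factors or Wald test, and with any single library left out. The SG12 response difference (671 and 705 before) had 463 and 773 without SGCTRL FBS replicate 2. LPDS in parental cells (282 and 301 before) had 115 and 44 without LPDS replicate 3, and turned without 2 other libraries. No filter gave 463 and 717 for SG21 against SGCTRL in LPDS (before 704 and 697). A spread from the compared groups alone gave 579 and 1099 for SGCTRL against parental cells in FBS (before 1057 and 1294) and 147 and 209 in LPDS, and the covariate 67 and 26 for LPDS in parental cells. With the library split term SG21 against SGCTRL in FBS had 56 and 101 (before 942 and 858). For the SG21 response difference, 2 and 4 before, the Wald test gave 24 and 8, no filter 2 and 9, and the compared groups alone 12 and 5. No change of scaling alone moved the median fold change of all entries by over 0.1. With uniquely aligned reads as library size the calls were 311 higher and 206 lower for LPDS in SG21 (before 240 and 251) and 52 and 85 for SGCTRL against parental cells in LPDS. Where a value moved, the cause was not tested.

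The Wald test gave 218 entries for SGCTRL against parental cells in LPDS and 32 for the SG21 response difference, no filter 162 and 11, and a spread from the compared groups alone 356 and 17, with 248 for LPDS in parental cells and 793 in SGCTRL. Uniquely aligned reads as library size gave 11 for the SG21 difference. With parental cells as control SG21 in FBS gave 3101 and the SG21 difference 88. The overlap of the knockout lines was 406 in FBS with parental cells as control for SG21 alone and 406 for SG12 alone, different sets with 190 entries in common, which are those called against both controls, and 1150 with parental cells for both. In LPDS it was 169 and 169, with 110 in common. With the library split term, which rests on SG21 in LPDS, the counts were 91 for SG21 in LPDS against FBS, 842 and 157 for SG12 and SG21 in FBS, and 200 for SG12 in LPDS. They were 133 and 1 for SGCTRL against parental cells in FBS and LPDS, 50 and 75 for the overlaps and 0 for the SG21 difference in edgeR. For that difference 578 were at an unadjusted p under 0.05, fewer than a 0.05 share of the 12822 tested. SG21 LPDS replicate 1 alone, a library assumed to vary like the other groups, gave 89, and 0 for the SG21 difference in edgeR. The own-name share as a covariate gave 93 for LPDS in parental cells, and 88 and 58 for SGCTRL against parental cells in FBS and LPDS. Without SG21 the overlap of lines was 74. Of 300 list tests by own name 44 passed, with 0 in camera at an estimated correlation, 73 in fry and 69 with parental cells as control, and by source gene 24 of 204 held with an estimated correlation.

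Reversed with parental cells as control were HMGCS1 for SG12 in LPDS (0.22), for SG21 in FBS (0.35) and in LPDS (0.27), and LSS for SG21 in FBS (0.52). Reversed with the library split term were UQCRB (-0.27), ATP5ME (-0.47), TMA7 (-0.22) and the NPC1 entry (-0.10) for SG12 in FBS. So were IDI1 (-0.87), UQCRB (-0.34), ATP5ME (-0.59) and TMA7 (-0.02) for SG21 in FBS, UQCRB for SGCTRL against parental cells in FBS (0.37), and the TNFAIP2 entry there (-0.67) and in LPDS (-0.54). NPC1 for SGCTRL against parental cells in FBS turned to -0.14 with the covariate.

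Leaving out a single library gave 159 to 864 for LPDS in parental cells, 152 to 201 in SGCTRL, 2058 to 3125 in SG12, 221 to 846 in SG21 and 35 to 57 in all 4 lines. In FBS it gave 2545 to 3127 for SG12 and 1319 to 1392 for SG21, with 473 to 634 in both, and in LPDS 927 to 1146, 1016 to 1222 and 176 to 272. For SGCTRL against parental cells it gave 1100 to 2470 in FBS and 24 to 86 in LPDS, and for the response differences 1019 to 1738 in SG12 and 0 to 250 in SG21 (0 in edgeR without any of several libraries, highest without SG21 LPDS replicate 1). The entry named TMEM97, which holds IFT20 reads, passed in 2 to 4 of 12 comparisons, 2 without SGCTRL LPDS replicate 2 or SG12 LPDS replicate 2.

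Pairing by replicate stays open. Same-number libraries had a median correlation of 0.0035. Centring by group ties the -0.0047 for other numbers to it. The replicate block raised the counts to 694, 341, 2941 and 579 for LPDS in parental, SGCTRL, SG12 and SG21 cells. For the knockout lines they were 3321 and 1893 in FBS and 1542 and 1471 in LPDS. They were 2430 and 135 for SGCTRL against parental cells, 1480 and 7 for the response differences, 708, 313 and 57 for the overlaps, 4 comparisons for the entry named TMEM97 and 45 list tests. It ended the call of IDI1 for SG12 in FBS (adjusted p = 0.0629) and no other named call.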

Other observations

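Of the genes listed for other cell types, 2 are read here through an opposite-strand entry. THY1, in the fibroblast list, was at 186 to 625 CPM in every library and is also expressed by some tumour lines, and LYZ, in the leukocyte list and read under ENSG00000257764, was at 0 to 0.977 CPM, under the background level. No hypothesis on another cell type was tested. The first 2 principal components of the log counts held 19.3% and 13.7% of the variance. Single libraries stood apart from their groups. SG12 FBS replicate 3 was at 6.47 on the first component, beside -30.27 and -30.72 for replicates 1 and 2, and the chi-square per degree of freedom between its counts and theirs was 12.2 and 10.2, beside 2.72 between them. Parental FBS replicate 2 was at -83.04, beside -36.31 and -52.76, with 13.1 and 8.79, beside 3.08. SG21 LPDS replicate 1 had 9.48 and 7.97, beside 3.15. Without SG12 FBS replicate 3, 3127 entries passed for SG12 against SGCTRL in FBS and 1738 for its response difference. Without parental FBS replicate 2, 180 passed for LPDS in parental cells and 1100 for SGCTRL against parental cells in FBS. No explanation of these libraries was tested. The share of reads aligned more than once was 10.8% to 19.6% in the 8 libraries with few ambiguous reads and 10.4% to 15.8% in the other 16.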
